A study of Schizosaccharomyces pombe with 28 samples.

How the data were processed

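The series holds 28 two-channel spotted arrays of the fission yeast Schizosaccharomyces pombe. Per the labels, both channels of every array held cDNA from independent samples of the same wild-type strain (h- leu1-32), grown to early-log phase in rich YES medium. Such an array is called a self-self hybridisation. Total RNA was extracted with hot phenol and reverse-transcribed from an oligo-dT primer with Cy3 or Cy5, per the labels. All 28 arrays form a single group, and the hybridisation number in each title (1 to 28) names the array here.

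The deposited values are log2 ratios of the channels, given per the labels as medians of log2 expression ratios. Per the labels, slides were scanned on a GenePix 4000A and read with GenePix Pro 4.0, the background was corrected, and flagged values and dim features were removed. The deposited table nevertheless has a value for every probe in every array, with 0 missing values, so which spots were dim cannot be told from it. The step that set array medians near 0, the channel used as numerator, and any dye swap are not given in the sources used here. Signs are therefore those of the deposited values and name no channel, and the tests of a mean assume that all arrays run the same way. After conversion to linear ratios, 99.99% of values lay within 0.02 units of the third decimal of a whole step, the precision at which they were rounded. Array medians ran from -0.30 in array 27 to 0.01. No spot intensities were used here, so intensity-dependent normalization could not be applied and signal over background is unknown. The number of arrays limits the precision.

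The table has 9858 probes, 2 for each of 4929 gene identifiers. The platform annotation gave a single gene for 9632 probes, several genes for 44 and none for 182, and no gene is named from a probe with several. Of the 4816 identifiers with a single gene, 4791 were found in the RefSeq gene table, which was used for current names and gene lengths. Each array was centred on its median and the 2 probes of a gene were averaged.

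Tests were fixed before the data were examined. The mean ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a robust prior, two-sided). The variance of each gene was tested against limma's robust prior over genes with an F tail probability. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as threshold. Of 30 gene lists fixed beforehand, 29 had at least 3 measured members. The list of genes encoded in the mitochondrion had 0. A further list enters the counts of lists but is not reported here. For each list, the median SD of its members was compared with 10000 random lists (two-sided), and the SD across arrays of the list's mean was compared with 10000 random lists matched on gene SD in 10 bins (one-sided). The mean ratios of a list's members were compared with those of all other genes with limma's camera at a preset inter-gene correlation of 0.01. Principal components were compared with 100 permutations of each gene's values across arrays. Gene means and SDs were correlated between odd-numbered and even-numbered arrays.

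On simulated data for 4929 genes, 100 genes shifted by a mean of 0.3 were recovered at 100% and 100 genes shifted by 0.1 at 77%. The simulated arrays were independent and lacked the sets of like arrays described below. These shares therefore do not give the recovery of mean shifts in the real arrays. The variance test recovered 97% of genes whose SD was multiplied by 2 when all gene SDs were equal, but 0% of them, and 1% of those multiplied by 4, with the real spread of gene SDs. A test added after seeing the data therefore compares the variance of a gene between arrays with the disagreement of its 2 probes. In simulation it recovered 40% of genes whose array SD equalled the probe noise and 96% of those at 2 times that noise, and 6.8% of its calls were false. Here too the simulated arrays were independent, and no error was shared by the 2 probes or among arrays. These shares therefore need not hold in the real arrays. Variation past this test is called reproducible between probes.

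Alternatives fixed beforehand were no centring, scaling of each array, coverage filters, removal of the 3 arrays of widest spread, an ordinary prior, a minimum absolute mean of 0.3, a median absolute deviation, a root mean square about 0, removal of the first principal component, other matching of random lists, a list median, an estimated inter-gene correlation and arrays 1 to 14 against 15 to 28. Clustering of the arrays (average linkage on 1 minus Pearson's r) was added after seeing the data and cut at 3 sets: arrays 1 to 8 with 19 and 20, arrays 9 to 18, and arrays 21 to 28. The labels do not give these sets. They serve as possible batches, as a random block or as fixed blocks, and are not study groups. Other alternatives added later were each probe alone, each set alone or left out, and all arrays but 25 to 28.

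Named genes followed a rule fixed beforehand: the 20 of highest SD, the 3 of highest SD in each list, the 8 most positive and 8 most negative means, the 3 of lowest SD, leu1, act1 and the mating genes. The rule asked for genes past the variance test. That test called 0 genes, so the 20 of highest SD are named without it and list members had to pass the probe test, a choice made after the values were seen. Further genes are marked where they appear.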

Results

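The arrays measured the ratio of transcript levels between independent wild-type samples in 28 self-self hybridisations, each with 4929 gene identifiers. The design implies the question of how far transcript levels differ among repeats of the same strain and medium, and which genes and gene groups do so. The labels describe the samples as independent. The arrays did not behave as 28 independent draws, however: the correlation across genes between arrays had a median of 0.657 within 3 sets (lowest 0.014) and 0.039 across them (highest 0.579), a gap that is partly built in, since the sets were cut by clustering these same correlations. P-values and SEs of means that treat the 28 arrays as independent are therefore too small, and all SEs given here do so. For tests of the mean, p-values with the sets as a block are given as well.

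The widest spread across arrays belonged to iron uptake genes. The ferroxidase gene fio1 (SPAC1F7.08) had an SD of 1.28 (n = 28) and ranged from -2.56 to 0.83 on the log2 scale, and the iron permease gene fip1 (SPAC1F7.07C) had an SD of 1.24 and ranged from -2.49 to 1.13. The ferric reductase gene frp1 had an SD of 1.14, the transporter genes str3 and str1 SDs of 1.08 and 0.91, and abc3, a vacuolar ABC transporter gene, 0.65. In arrays 9 to 18 fio1 lay between -2.56 and -2.19, and in arrays 21 to 28 between 0.49 and 0.83. The 2 probes of fio1 correlated at 0.996 across arrays, those of fip1 at 0.984 and those of frp1 at 0.942.

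**Figure D1:**
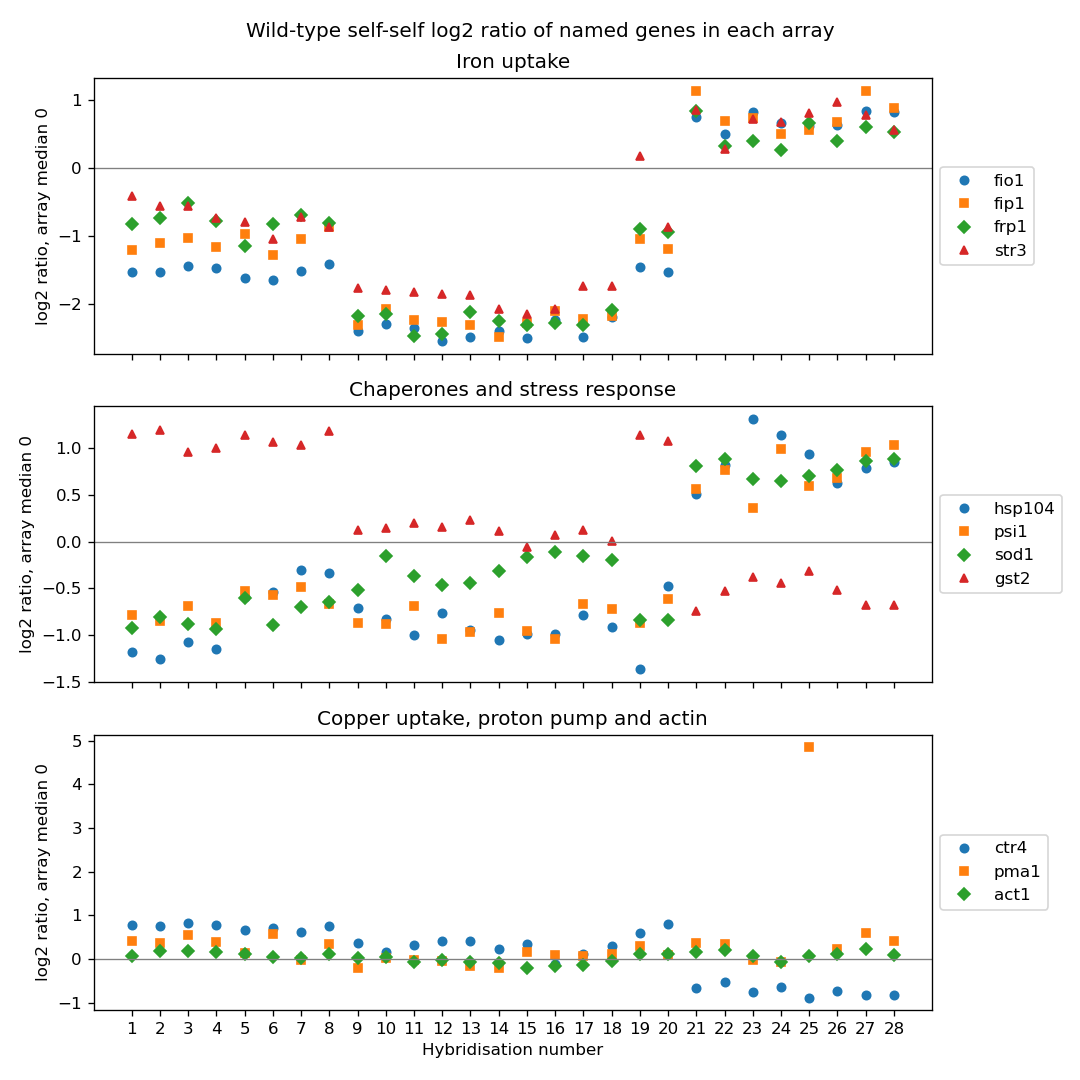
Log2 ratio of named genes (y axis, centred on the array median) against hybridisation number (x axis), a point per gene and array. fio1 lies between -2.56 and -2.19 in arrays 9 to 18 and between 0.49 and 0.83 in arrays 21 to 28, while act1 stays between -0.21 and 0.23 and pma1 reaches 4.86 in array 25.

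Chaperone and stress genes also spread widely. The disaggregase gene hsp104 had an SD of 0.85 and ranged from -1.37 to 1.31, the DnaJ-type co-chaperone gene psi1 had an SD of 0.72 and the Hsp90 co-chaperone gene sti1 an SD of 0.62. The superoxide dismutase gene sod1 (SD 0.66) and the glutathione S-transferase gene gst2 (SD 0.68) lay on opposite sides of 0: in arrays 21 to 28 sod1 was between 0.65 and 0.89 and gst2 between -0.74 and -0.32. The copper transporter gene ctr4 had an SD of 0.61 and lay between -0.88 and -0.53 in the same arrays. Of the 20 genes of highest SD, the others were tef101 (1.18), tef102 (1.16) and tef103 (0.78), which encode elongation factor eEF1A, the proton pump gene pma1 (0.91), hry1 (0.67), ost4 (0.65), mfs3 (0.63) and mrpl32 (0.60). ost4 lay between 1.10 and 1.65 in arrays 1 to 6 and 19 but between 0.21 and 0.35 in arrays 7, 8 and 20. mrpl32 split likewise, at 0.96 to 1.40 and 0.06 to 0.30.

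The spread of the eEF1A genes and pma1 came from a few arrays. In array 25, pma1 stood at 4.86, against at most 0.59 in the other arrays, and its SD without array 25 was 0.237. Without arrays 25 to 28 the SDs of tef101, tef102 and tef103 were 0.187, 0.215 and 0.145. In array 24 tef101, tef102 and pma1 stood at -0.065, -0.065 and -0.061, and in array 3 tef102 and tef103 both at 0.319. In array 13 tef101, tef102 and tef103 lay apart, at -0.233, -0.522 and -0.021. Spot intensities were not used, so whether a signal ceiling held down these SDs cannot be told. The 2 probes of tef103 correlated at 0.170, and its variation was not reproducible between probes (adjusted p = 0.488).

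At the other end, SPBC12D12.05C had an SD of 0.054, img1 0.061 and SPBP4H10.14C 0.062. The actin gene act1 had an SD of 0.12. leu1, which encodes isopropylmalate dehydrogenase and is mutated in this strain, had an SD of 0.29 and ranged from -0.37 to 0.65. Over all 4929 genes the median SD was 0.165 (quartiles 0.126 and 0.219), and 38 genes had an SD of at least 0.5.

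The planned limma variance test called 0 genes. The smallest adjusted p was 0.331, 208 genes had an unadjusted p under 0.05 (210 with the ordinary prior), and in simulation the test recovered almost no genes at the real spread of SDs. The added probe test found variation reproducible between probes in 2617 genes (53.1%), and in 1145 genes (23.2%) once the 3 sets were removed as fixed blocks.

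Gene lists differed in spread. Iron uptake genes had a median SD of 0.475 (12 genes, of which 11 varied reproducibly) and copper uptake genes 0.442 (3 of 4), against 0.165 and 0.167 in random lists. The list called iron uptake here is that of iron starvation Fep1 targets, and not all its members act in uptake itself, among them abc3 and php4. Chaperones had a median SD of 0.270 (17 of 21), glycolysis and fermentation genes 0.256 (15 of 17), core stress genes 0.256 (16 of 24), ribosomal protein genes 0.228 (111 of 124) and translation factor genes 0.214 (26 of 36). These 7 lists lay above random lists, with adjusted p = 0.00145 for iron uptake, chaperones, core stress and ribosomal proteins (whose unadjusted p is the smallest the random lists allow), 0.00232 for copper uptake, 0.0058 for glycolysis and 0.00725 for translation factors. Random lists draw genes singly, so p-values of list SDs are too small where members move together. Members correlated on average at 0.66 for iron uptake, 0.60 for copper uptake, 0.43 for ribosomal proteins, 0.41 for glycolysis and 0.35 for chaperones. For core stress the average was 0.11 and for translation factors 0.034. Retrotransposons and wtf genes lay below, with a median SD of 0.118 (20 genes, of which 5 varied reproducibly, adjusted p = 0.00725). This list holds wtf genes, a family of spore killers, and a single retrotransposon, Tf2-11. Tf2-11 itself ranged from -0.77 to 0.56, so the low spread is that of the wtf genes. With the sets removed, 4 lists still differed: chaperones (adjusted p = 0.0305), ribosomal proteins (0.0029), glycolysis (0.0305) and translation factors (0.0029). Iron uptake (0.368), copper uptake (0.619), core stress (0.227) and retrotransposons and wtf genes (0.568) did not. Structure remained within sets. In the first set, arrays 1 and 2 correlated at 0.846 and 7 and 20 at 0.81, but 1 and 20 at 0.513. In the third, arrays 21 and 27 correlated at 0.699 and 25 and 26 at 0.71, but 21 and 26 at 0.014. Ribosomal proteins averaged 0.204 to 0.397 in arrays 21, 22, 27 and 28 and -0.101 to 0.037 in arrays 23 to 26. Glycolysis genes averaged 0.302 to 0.464 and -0.007 to 0.114 there. Passing with the sets removed therefore does not exclude a batch within a set. The call for translation factors was lost with probe 1 alone (adjusted p = 0.543) and without arrays 25 to 28 (0.113), that for glycolysis with probe 2 alone (0.067) and without arrays 25 to 28 (0.191), and that for retrotransposons and wtf genes with either probe alone (0.543 and 0.0551). Other choices made before the data were seen ended calls too: the median absolute deviation those for chaperones (0.111) and translation factors (0.213), the root mean square about 0 those for glycolysis (0.0689) and retrotransposons and wtf genes (0.0555), no centring that for glycolysis (0.0606), and removal of the first principal component those for translation factors (0.0754) and retrotransposons and wtf genes (0.396).

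**Figure D2:**
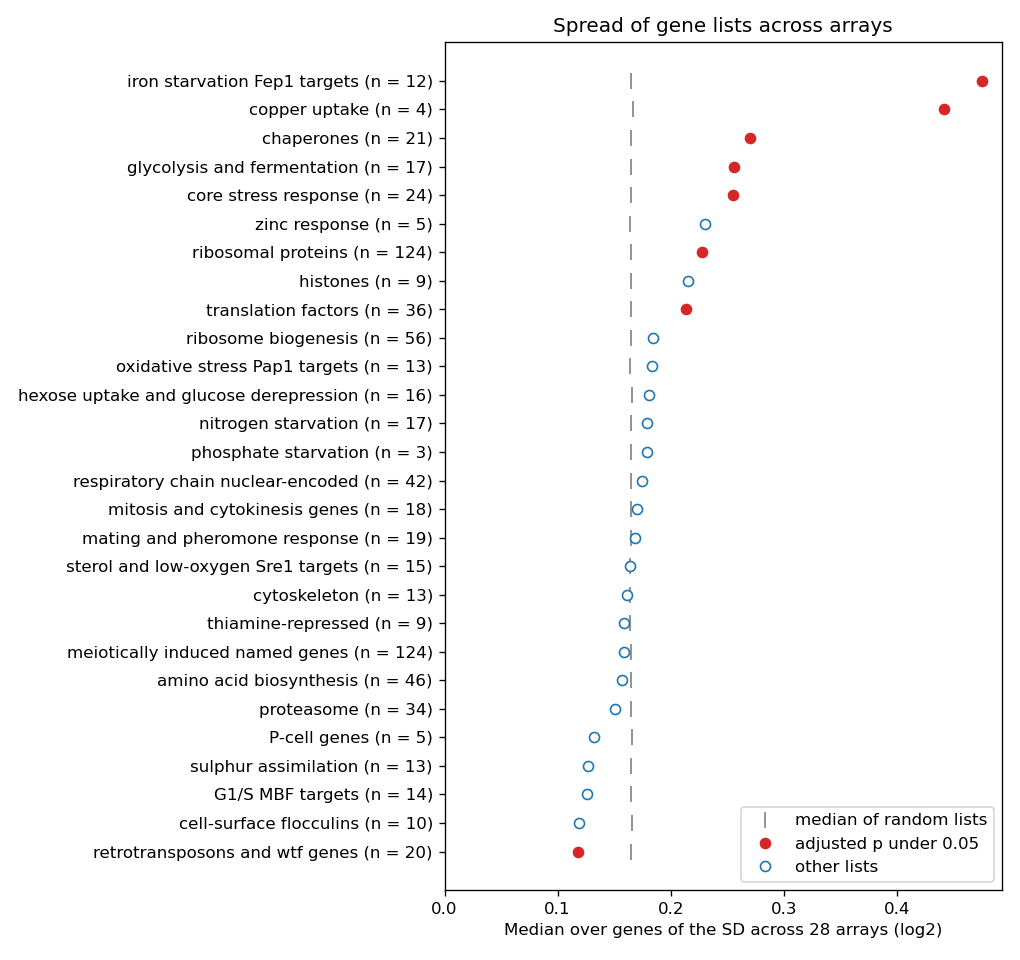
Median over the members of each gene list shown of the SD across 28 arrays (x axis, log2), with the number of measured members beside each name on the y axis. Filled points are the 8 lists that differed from random lists at an adjusted p under 0.05, and grey bars mark the median of random lists. Iron starvation Fep1 targets, called iron uptake in the text, lead at 0.475.

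Among glycolytic and fermentative genes, the pyruvate decarboxylase gene pdc201 had the highest SD (0.54, range -0.18 to 1.41), ahead of gpd3 (0.35) and the aldolase gene fba1 (0.34). Of the ribosomal protein genes past the probe test, rpl2502 (0.49), rpl1602 (0.40) and rpl4102 (0.36) had the highest SDs. Of the oxidative stress list, srx1, which encodes a sulfiredoxin, had an SD of 0.56 and obr1 0.50. The list itself, with a median SD of 0.184, did not differ from random lists (adjusted p = 0.644).

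Members of most lists moved together from array to array. The mean of the iron uptake list had an SD of 0.58 across arrays against 0.094 for random lists matched in bins of gene SD, and its members correlated at 0.662 on average. For chaperones the SD of the list mean was 0.25 against 0.07, for ribosomal proteins 0.16 against 0.039, for histones 0.17 against 0.069 and for amino acid biosynthesis 0.11 against 0.033. The adjusted p was 0.000967 for histones and 0.00058 for the other 4 lists, whose unadjusted p is the smallest the random lists allow. The highest bin of gene SD also holds genes of far lower SD than fio1, fip1, frp1 and hsp104. For iron uptake and chaperones the random values are therefore too low and the p-values too small. The same holds for any list with members of very high SD. In all, 23 of 29 lists varied together, 15 with no centring and 15 with the sets removed, and 14 passed both with and without removal of the sets. With the sets removed, ribosomal proteins (adjusted p = 0.000967), amino acid biosynthesis (0.000967), histones (0.00181) and proteasome genes (0.00181) still varied together, though histones (0.0527) and proteasome genes (0.0613) did not pass with probe 1 alone, while iron uptake (0.052), chaperones (0.0984) and core stress genes (0.675) did not pass. With probe 1 alone 9 lists passed and with probe 2 alone 14, with 8 in both.

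Some genes had a mean ratio away from 0, given here with SEs that treat the 28 arrays as independent and are too small. On the negative side, fio1 averaged -1.20 (SE 0.23, n = 28), fip1 -0.97 (SE 0.22), frp1 -0.96 (SE 0.21) and str3 -0.71 (SE 0.20), followed by the flocculin gene pfl3 at -0.63 (SE 0.06), SPAC17A2.10C at -0.52 (SE 0.06) and SPAC56F8.15 at -0.51 (SE 0.06). On the positive side, SPAC1039.02 averaged 0.70 (SE 0.10), the4 0.63 (SE 0.07), mfs3 0.58 (SE 0.11), tef101 0.54 (SE 0.21), SPAC750.01 0.53 (SE 0.06), urg2 0.48 (SE 0.06) and tif212 0.48 (SE 0.05). pfl3 was below 0 in 27 arrays and urg2 above 0 in 28, whereas fio1, fip1 and frp1 were above 0 in 8. With the sets as a random block in limma, the adjusted p was 0.00056 for pfl3, 0.0103 for fio1, 0.0286 for frp1, 0.00552 for SPAC1039.02, 0.00502 for the4, 0.0148 for urg2, 0.0152 for SPAC750.01, 0.00532 for SPAC17A2.10C and 0.0127 for SPAC56F8.15. The block fit uses a single correlation for all genes, whereas at least 98.1% of the variance of fio1 and frp1 and 71.5% to 91.1% of that of the other 7 genes lay between sets, so these block p-values are too small. fio1 averaged -1.52, -2.40 and 0.70 in the 3 sets and frp1 -0.82, -2.27 and 0.50, which leaves no mean below 0 common to the sets. The other 7 kept their sign in each set, but in arrays 21 to 28 4 of them did not pass: SPAC1039.02 averaged 0.04 (adjusted p = 0.547), the4 0.09 (0.108), SPAC17A2.10C -0.05 (0.422) and SPAC56F8.15 -0.12 (0.0554). The adjusted p with the block was 0.0517 for fip1, 0.183 for str3, 0.137 for mfs3, 0.639 for tef101 and 0.113 for tif212. Without arrays 25 to 28, where its probes reached extreme values, tef101 averaged 0.11. The 2 probes of SPAC750.01 correlated at -0.497 and averaged 0.73 and 0.32, those of SPAC17A2.10C averaged -0.83 and -0.20, and those of str3 -0.42 and -0.99. act1 (0.04, SE 0.02) and leu1 (0.11, SE 0.05) did not pass, with adjusted p = 0.108 and 0.0876 in limma, and 0.681 and 0.679 with the sets as a block.

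In the limma fit of 28 arrays 2553 genes passed, 1370 with a mean above 0 and 1183 below, of which 70 and 36 had an absolute mean of at least 0.3. With the sets as a random block (correlation 0.48) 71 passed, 31 above and 40 below, all among the 2553. The block fit has few sets to judge a mean by and uses that single correlation for all genes. Its p-values may therefore be too small, above all for genes that differ most between sets, and the 71 too many. The ratio kept a single sign in all 28 arrays for 52 genes, 25 above 0 and 27 below. Of the 25, 8 were ribosomal protein genes of the fixed list, and none of those below were.

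By list, 97 of 124 ribosomal protein genes had a mean above 0 past the test, 0 below and 27 did not pass (101 above when adjusted over the list alone). Their average was 0.19. Translation factors averaged 0.17 (25 of 36 above, 0 below), ribosome biogenesis genes 0.10 (31 of 56 above, 4 below), proteasome genes 0.10 (21 of 34 above, 4 below) and nuclear-encoded respiratory genes 0.08 (18 of 42 above, 1 below). Iron uptake genes averaged -0.46 (11 of 12 below), though 0.30 in arrays 21 to 28, mitosis and cytokinesis genes -0.08 (8 of 18 below), Sre1 targets -0.07 (6 of 15 below), though 0.04 in arrays 1 to 8 with 19 and 20, meiotically induced genes -0.06 (64 of 124 below, 11 above) and retrotransposons and wtf genes -0.05 (9 of 20 below). Counts by list from the block fit share the limit given above for that fit. With the sets as a random block, 14 ribosomal protein genes passed above 0 and 2 iron uptake genes below (fio1 and frp1). Also passing were 1 respiratory gene above and 1 meiotically induced gene below, and 0 members of the other lists named here. Against all other genes, camera with a preset correlation called 11 lists, these among them. With an estimated correlation, translation factors kept the call (adjusted p = 0.0106) and the other 10 lost it, with adjusted p = 0.235 for ribosomal proteins with an estimated correlation and 0.394 for iron uptake. Ratios tended to fall with gene length, with Spearman's rho across genes from -0.241 to 0.031 among arrays. Means of genes and lists were not adjusted for length, so its part in these shifts is open.

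Genes of mating and the pheromone response stayed near the typical spread. The 19 members had a median SD of 0.168 (adjusted p = 0.933) and the 5 measured P-cell genes 0.132 (adjusted p = 0.525). Of the members past the probe test, the protease gene sxa1 (0.28), the regulator gene ste11 (0.26) and ste4 (0.23) had the highest SDs. The pheromone precursor genes mfm1, mfm2 and mfm3 had SDs of 0.17, 0.18 and 0.17, and the P-factor gene map2 0.12. The kinase gene byr1 had an SD of 0.30, not past the probe test (adjusted p = 0.0596), averaged 0.38 (SE 0.05, adjusted p = 1.35e-06 in limma, 0.186 with the sets as a block) and was above 0 in 28 arrays.

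The arrays shared structure beyond independent gene noise. Of the principal components, 3 exceeded the permutations, holding 40.3%, 21.5% and 6.15% of the variance, against at most 5.37% for the first permuted component. Correlations between arrays ran from -0.202 to 0.896. Gene means correlated at r = 0.910 (rho = 0.892) between odd and even arrays and gene SDs at r = 0.844 (rho = 0.775), across genes, which are not independent replicates. Odd and even arrays divide each set equally, which favours agreement. Between arrays 1 to 14 and 15 to 28 these fell to r = 0.606 and r = 0.493, and over 100 random splits into 14 and 14 arrays they ran from 0.461 to 0.944 for means and from 0.543 to 0.852 for SDs.

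**Figure D3:**
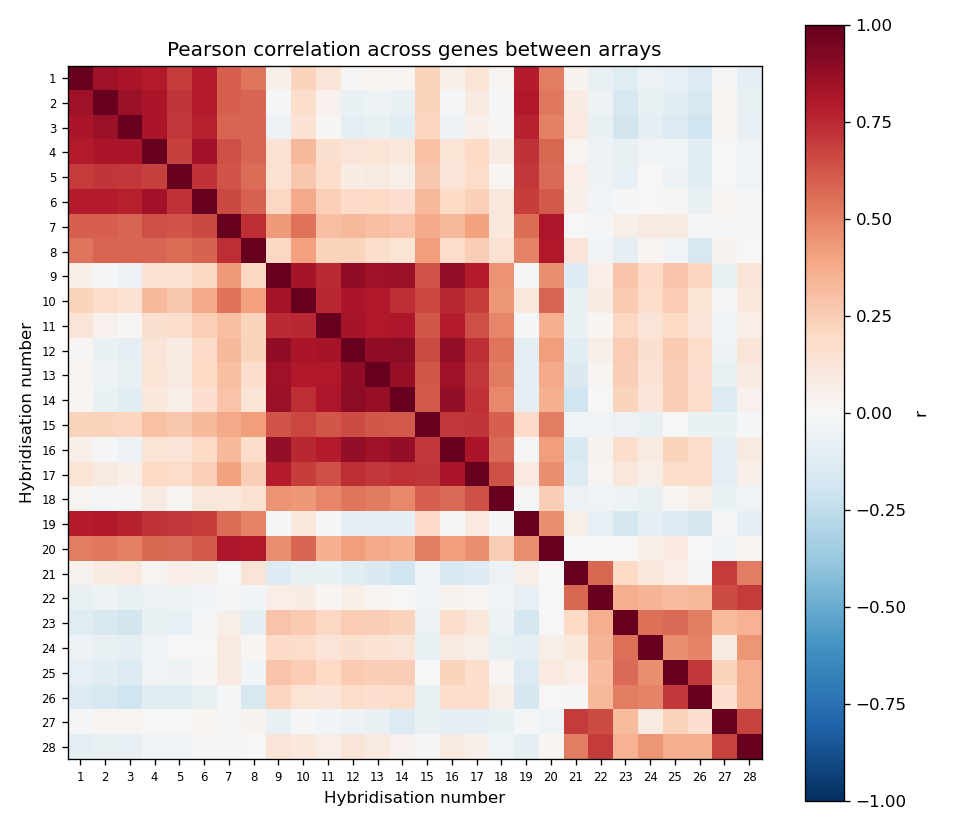
Pearson correlation across genes between each pair of arrays (colour, from -1 to 1), with hybridisation number on both axes. Blocks of high correlation hold arrays 1 to 8 with 19 and 20, arrays 9 to 18 and, more loosely (median 0.361), arrays 21 to 28.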

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

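The array sets, the probes taken singly and the removal of arrays 25 to 28 were chosen after seeing the data. Coverage filters and matching on coverage removed no gene, since no value was missing, and so test nothing. No paired analysis was possible because there is a single group of arrays. The count of genes with a mean away from 0 (2553) was 106 with a minimum absolute mean of 0.3, 71 with the sets as a random block and 1305 in arrays 21 to 28 alone, and stayed between 2276 and 3244 under the other alternatives. Genes past the variance test (0) were 11 with the first principal component removed, 3 with the sets removed and 2617 by the probe test. That probe count was 1145 with the sets removed, 1628 without arrays 9 to 18 and 2410 without arrays 25 to 28. Lists of differing SD (8) numbered 4 with the sets removed, 0 in the first set alone, 0 in the second and 5 in the third. Lists varying together (23) numbered 15 with no centring, 15 with the sets removed, 9 with probe 1, 14 with probe 2, 4 in the first set and 10 in the third. Shifted lists (11) numbered 1 with an estimated correlation. Components above permutation (3) numbered 8 with the sets removed. Repeatability of means (0.910) was 0.606 between arrays 1 to 14 and 15 to 28, and that of SDs (0.844) was 0.493 there and 0.762 with the median absolute deviation. The cause of these changes was not tested.

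Of the 2553 called genes, 101 had probe means of opposite sign. Among the lists and genes compared, and counting those where the value over all arrays or that in the set passed its test, directions turned in single sets of arrays. In arrays 21 to 28 the mean was 0.17 for core stress genes, 0.32 for chaperones, 0.30 for iron uptake and -0.40 for copper uptake, and 0.70 for fio1, 0.78 for fip1, 0.50 for frp1, 0.70 for str3 and -0.13 for mfs3. In arrays 9 to 18 it was -0.14 for histones, -0.11 for amino acid biosynthesis, -0.016 for tef101, -0.13 for leu1 and -0.073 for act1, and the median SD of ribosomal proteins was 0.109, below random lists but not past the test (adjusted p = 0.849). In arrays 1 to 8 with 19 and 20 the median SD of glycolysis genes was 0.108, also below (adjusted p = 0.674). Means of 2 lists changed sign while staying on the same side of other genes: Sre1 targets averaged 0.04 in arrays 1 to 8 with 19 and 20 (adjusted p = 0.891) against -0.07 over all arrays, and nitrogen starvation genes -0.10 in arrays 9 to 18 (adjusted p = 0.0369) against 0.013. Signal over background is unknown, so its effect on dim genes cannot be given.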

Other observations

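Some genes varied within the sets of arrays, reproducibly between probes, and were chosen for mention after their values were seen. The ribosome biogenesis gene bud22 ranged from -1.16 to 0.59, with a within-set SD of 0.38, and the signal recognition particle gene srp21 from -1.41 to 0.44, with 0.38. ura1, of pyrimidine synthesis, had a within-set SD of 0.34: it lay between -0.06 and 1.58 in arrays 1 to 8 with 19 and 20 and between -0.22 and 0.16 elsewhere. The fatty acid elongase gene elo2 ranged from -0.49 to 1.10 and the ribosomal protein gene rpl1602 from -0.44 to 0.92. rpl1602 stood at 0.51 to 0.92 in arrays 1 to 6 and 19 but at -0.17 to 0.21 in arrays 7, 8 and 20. Variation within sets may therefore follow smaller groups of arrays. Genes on a single side of 0 in 28 arrays included the ubiquitin fusion gene ubi3, with a mean of 0.47 (SE 0.04), rpl42 at 0.41 (SE 0.03), vma6, a vacuolar ATPase subunit gene, at -0.50 (SE 0.04; probe means -0.88 and -0.12), and the microtubule-associated protein gene dis1 at -0.32 (SE 0.03; probe means -0.53 and -0.10).

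All tests of explanations below were chosen after the pattern each concerns was seen. The list of iron-using genes, the test of their side of 0 and the test of gene length were written down before their own results were seen, and the other tests after. No biological explanation is given by the design, which has a single group.

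Iron uptake genes ranged over several log2 units, and a faulty probe is argued against by the median correlation of 0.886 between the 2 probes of a gene over the 12 genes, and a dye bias of constant size, with or without swapped dyes, by absolute list means from 0.187 to 1.21, 6.46 times apart. A difference in iron supply between the cultures of an array may be the source: 23 iron-using genes lay on the other side of 0 from the iron uptake list in 22 arrays, but random lists of like SD did so in a median of 17 and reached 25 at their 95th percentile (one-sided p = 0.204), so the planned test leaves this open. A version that set each list about its own mean was run first, in place of the planned one. It gave 12 arrays against a random median of 14 and a 95th percentile of 22 (one-sided p = 0.658). This version showed no opposite movement of the iron-using genes but cannot exclude it. In arrays 1 to 8 with 19 and 20 the iron uptake list lay between -0.53 and -0.29, close to its average of -0.46, so its side there is poorly defined. A dye bias that differed between arrays and an effect on iron uptake genes alone stay open.

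The arrays fell into 3 sets. Noise of single arrays is argued against by the median correlation of 0.406 between probe 1 on an array and probe 2 on another array of the same set (0.024 across sets), while the ranges of probe disagreement overlapped, with 11 arrays in the range common to the sets, a comparison tried first that decided nothing because 14 had been asked for. A trend with gene length is argued against, as the source of the sets alone, because removing it left 1.008 of the gap between within-set and across-set correlations. Arrays of a set may share RNA or cultures grown together: within sets, iron uptake genes had a median SD only 1.19 times that of all genes, and clustering without these genes put all 28 arrays in the same sets. Shared RNA, shared cultures and a shared hybridisation batch cannot be separated with these values, and the labels describe the samples as independent.

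In array 25, 12 probes of 9 genes, among them tef101, tef102, tef103, pma1 and several ribosomal protein genes, lay between 4.83 and 4.89, and the next highest probe at 1.15. A signal ceiling is a candidate explanation, since the 12 values spread over only 0.052. These values are ratios, however, and without the channel signals a ceiling cannot be told from another limit on the deposited values. Near-identical copies of the eEF1A gene are argued against, for array 25 alone, by the 7 of these probes that belong to other genes. In arrays 26, 27 and 28, the only others with a probe above 3, eEF1A probes made up 3 of 4 (5.31 to 5.39), 2 of 2 (3.69 and 3.23) and 3 of 3 (3.02 to 3.05), so copies stay open there, and the gap in array 27 goes against a common ceiling in that array. No biological explanation was tested.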
